A study of Mus musculus with 9 samples.

How the data were processed

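RNA was measured by bulk sequencing in 9 pancreas libraries of female KC mice, 3 on each of 3 diet schedules (CD, DIO and DIO-CD). Per the labels, RNA was extracted with RNeasy kits and on-column DNase digestion, and libraries were made by Novogene with oligo(dT) selection, Ribo-Zero removal of ribosomal RNA and random hexamer priming. Strand marking was not stated. The labels name the DIO-CD samples DIOCD, while the columns of the value table carry CDDIO, and these columns were taken to be the DIO-CD group because no other group was left. The column names put the diets in the other order, and the order of the labels, DIO first, was used and could not be checked from the values. The submitters' processing notes name HISAT2, featureCounts and DESeq2 and the mouse builds mm10 and GRCm38, without versions or roles. The deposited values are a signal in normalized counts, gene counts divided by 1 size factor per sample. Every value was within 0.001 of a whole multiple of 1 step per library (largest distance 0.000891), so whole reads were recovered by dividing by that step. The step, the normalized value of 1 read, was 2.89, 1.80 and 1.29 in CD 1 to 3, 0.485, 0.351 and 0.332 in DIO 1 to 3 and 1.58, 0.634 and 2.16 in DIO-CD 1 to 3. Size factors computed with DESeq2 from the recovered reads matched the deposited ones to a ratio of 0.999 to 1.001. The normalized totals were 73.4, 44.6 and 33.5 M in CD, 13.9, 11.9 and 11.6 M in DIO and 46.9, 28.9 and 36.3 M in DIO-CD, so the scale holds the typical gene level rather than the total. Intervals and floors of 3 reads cover counting error only, and a read is not known to be an independent molecule.

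The table held 27179 genes by Entrez ID, of which 20840 were above 0 in any library. No symbol was given for 1314 genes, and these took at most 0.193% of the reads of any library. Coordinates are those of GRCm38.p6 in RefSeq, matched by Entrez ID for 25275 genes. The samples are numbered without a statement that numbers pair them across groups, so no pairing was used. A fit with the number as a block was run as an alternative. All 9 libraries carried 1 batch label, so by the labels all comparisons lie within that batch.

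Genes with a mean of at least 10 normalized counts (15524, of which 178 had no symbol) were tested with limma 3.58.1 (R 4.3.3) on log2 of the value plus 1. All 9 libraries entered 1 fit with a trend of the variance on the mean, 3 pairwise comparisons and an F test among the 3 diets, and p was adjusted by the Benjamini-Hochberg method with a threshold of 0.05 within each comparison. Before the data were examined, 32 gene lists with 594 members (587 distinct genes, 566 members tested) were fixed, and camera tested each against all other genes with a preset correlation between genes of 0.01 and again with an estimated one, adjusted over the 32 lists. Counts adjusted over the list alone use the members of that list only. The intervals of list means are 95% intervals from an ordinary linear model of the mean of the members on the diet groups. Named genes followed a rule fixed at the same time: among genes past the threshold with a mean of at least 100, no overlap between the libraries of both groups (10% of genes by chance) and not a predicted gene, pseudogene or antigen receptor segment, the 12 largest rises and 12 largest falls. Where fewer than 5 passed, the 6 smallest unadjusted p in each direction were named. The examples of a list were the 2 to 4 members with the smallest p, and 21 genes were named whatever their result. Cth, Fgf21, Cpa1, Ptf1a and Flna were given coordinates as the genes described most fully. Shares of reads were compared by two-sided exact permutation tests. Correlations of fold changes were set against 1000 simulated draws of unchanged groups, since the comparisons share libraries.

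Tested on counts simulated with the levels, spread and size factors of these libraries, the limma settings recovered 2.04%, 63.3%, 68.0% and 79.6% of genes changed 2-fold, 4-fold, 8-fold and 16-fold in DIO against CD, with 0 false calls, and 2.04%, 61.2%, 72.0% and 79.6% in DIO-CD against DIO, with 3 false calls. With no list changed camera called 0 of 32, and with 1 list lowered it called 1, that list. The genes were simulated independently of each other, whereas the estimated correlation was 0.765 in the enzyme list. The simulation therefore does not show how often camera calls unchanged lists of correlated genes. Alternatives were a pseudocount of 0.5 or 8, no filter or a mean of at least 50, quantile normalization, equal library totals, equal upper quartiles, the replicate block, array weights, no trend, a fit over the 6 samples of the compared groups, each library left out in turn, fry and an estimated correlation for the lists, and edgeR 4.0.16 (quasi-likelihood) and DESeq2 1.42.0 on the recovered reads. Added after the data were seen were reads thinned to equal worth per read and a fit without CD 3 and DIO-CD 2. Figures were drawn with matplotlib 3.10.9 (Python 3.11.15, numpy 2.4.6). Of the list members, 28 were below the filter or absent and were not tested. The medians and camera adjusted p of the lists not given in the report were, for DIO-CD against DIO, -0.32 and 0.0933 (interferon), -0.06 and 0.887 (gastric-type lesion), -0.24 and 0.103 (ductal), 0.36 and 0.0947 (adipocyte), -0.11 and 0.535 (endothelial), -0.37 and 0.535 (mesothelial), 0.37 and 0.535 (erythroid), -0.18 and 0.887 (intestinal), -0.76 and 0.887 (liver), -0.09 and 0.887 (Schwann cell), 0.01 and 0.535 (lipid synthesis), 0.26 and 0.0933 (fatty acid oxidation) and -0.06 and 0.611 (hypoxia). For DIO-CD against CD they were 0.58 and 0.0532 (tuft cell), 1.18 and 0.143 (B cell), 0.81 and 0.600 (neutrophil), 0.22 and 0.345 (YAP and TAZ), 0.01 and 0.847 (cytokine), 0.41 and 0.193 (interferon), 0.06 and 0.491 (cell cycle), 0.33 and 0.143 (gastric-type lesion), -0.05 and 0.143 (ductal), 0.10 and 0.714 (islet), 0.01 and 0.897 (adipocyte), 0.20 and 0.0750 (endothelial), -0.33 and 0.623 (mesothelial), -0.74 and 0.130 (erythroid), 0.70 and 0.623 (intestinal), -0.94 and 0.130 (liver), 0.30 and 0.719 (Schwann cell), -0.16 and 0.419 (KRAS and ERK), 0.29 and 0.143 (fatty acid oxidation), -0.19 and 0.109 (hypoxia) and 0.10 and 0.897 (immediate early). None of the lists whose median, mean and camera direction differed in sign passed. They were the macrophage, Schwann cell and fatty acid oxidation lists in DIO against CD, the gastric-type lesion, intestinal, lipid synthesis and hypoxia lists in DIO-CD against DIO, and the adipocyte, Schwann cell, cell cycle, KRAS and ERK and immediate early lists in DIO-CD against CD.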

Results

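The 9 libraries came from the pancreas of female KC mice, which carry a mutant Kras allele switched on in the pancreas by Cre recombinase made from the p48 (Ptf1a) locus and develop precursor lesions of pancreatic cancer. The mice were grouped by diet, with 3 libraries per group. CD mice ate a low-fat control diet for 21 weeks, DIO mice ate a high-fat diet that induces obesity for 21 weeks, and DIO-CD mice ate the DIO diet for 8 weeks and then the control diet for 13 weeks. This order is that of the labels, while the columns of the value table read CDDIO. By its title, the series asks what a diet that brings body weight back to normal does to pancreatic tumour development sped up by obesity. The labels number the samples 1 to 3 in each group and do not say that each came from a separate animal, so the tests measure the spread between samples. All 9 carry the same batch label. The libraries held 25.4, 24.8 and 25.9 M reads assigned to genes in CD 1 to 3, 28.7, 33.8 and 34.8 M in DIO 1 to 3, and 29.7, 45.5 and 16.8 M in DIO-CD 1 to 3. Levels below are normalized read counts with the SD over n = 3, and fold changes are log2 with the standard error of the limma fit.

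The make-up of the RNA differed between the diets. Transcripts of 31 acinar digestive enzymes, the proteins that acinar cells secrete, took 68.6% ± 8.43 (SD, n = 3) of the reads in CD, 16.0% ± 4.18 in DIO and 64.6% ± 5.01 in DIO-CD. The share was 77.1%, 68.4% and 60.2% in CD 1 to 3, 20.8%, 13.5% and 13.7% in DIO 1 to 3, and 69.8%, 59.8% and 64.2% in DIO-CD 1 to 3. The DIO libraries did not overlap with those of either other group, and a two-sided exact permutation test gave p = 0.1 for both comparisons, the smallest that 3 against 3 allows. The exact p was 0.6 for DIO-CD against CD. Mitochondrial mRNA took 0.742% ± 0.324 of the reads in CD, 2.48% ± 0.700 in DIO and 1.50% ± 0.157 in DIO-CD (exact p = 0.1 for each pair). These are shares of all reads and so depend on the share that the enzymes take. The share among reads outside the enzymes was not tested, so the order of the diets there is not given by these values. The precursor of ribosomal RNA, Rn45s, took 1.45% ± 0.344, 1.31% ± 1.35 and 1.02% ± 0.620 (exact p = 0.9 for DIO against CD and for DIO-CD against DIO, and 0.4 for DIO-CD against CD). Outside the enzymes, the reads numbered 5.82, 7.83 and 10.3 M in CD 1 to 3, against 22.7, 29.2 and 30.0 M in DIO 1 to 3 and 8.97, 18.3 and 6.02 M in DIO-CD 1 to 3. Of 1562 genes with a mean of 50 to 100 normalized counts, 22.3% had no read in CD 1, 9.22% in CD 2 and 1.73% in CD 3, and 0.0640% to 0.320% in the DIO libraries. Transcripts of adipocytes stood apart in CD 3 and DIO-CD 2, where the mean log2 level of 18 adipocyte genes was 9.01 and 9.68, against 5.58 to 7.75 in the other libraries.

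**Figure D1:**
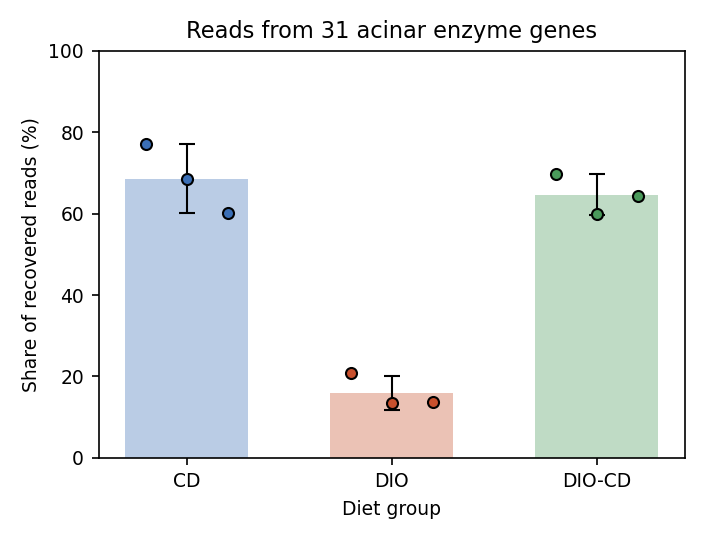
Share of recovered reads (%) from 31 acinar digestive enzyme genes in each library (points), with the mean of each diet group (bars) and the SD (error bars, n = 3). The 3 DIO libraries lie between 13.5% and 20.8%, and the other 6 libraries between 59.8% and 77.1%.

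The first comparison, DIO against CD, asks what the high-fat diet does to the KC pancreas, and transcripts of acinar cells were lower in DIO. All 31 digestive enzymes had lower levels in DIO, and 27 of them fell over all genes tested (31 adjusted over the list alone), with a median log2 fold change of -3.99 (camera adjusted p = 2.51e-28, and adjusted p = 0.248 with an estimated correlation). Quantile normalization, which gives all libraries the same distribution of values up to the highest, left a median of -1.19. Cpa1 (Entrez ID 109697; chromosome 6, 30639218 to 30645361), a carboxypeptidase of pancreatic juice, had 114967 ± 60345 normalized counts in DIO and 2341870.0 ± 898168 in CD, a log2 fold change of -4.40 ± 1.11 (limma adjusted p = 0.0388). The elastase Cela1 had -4.53 ± 1.03 (adjusted p = 0.0264), and the secretory phospholipase Pla2g1b -4.26 ± 0.53 (adjusted p = 0.000657). The zymogen granule protein gene Cuzd1 fell by 4.32 (adjusted p = 0.000186), and the amylase gene copies Amy2a1, Amy2a2 and Amy2a3 had log2 fold changes of -4.55, -4.78 and -4.40, where reads shared between such near-identical copies make the values of single copies uncertain. The call for Cpa1 ended without CD 2, DIO 1, DIO 2 or DIO 3 (adjusted p = 0.0894, 0.0527, 0.160 and 0.166), and that for Cela1 without CD 2, DIO 2 or DIO 3 (0.0684, 0.124 and 0.139). Quantile normalization also ended both calls, with log2 fold changes of -0.49 (adjusted p = 0.627) for Cpa1 and -0.85 (0.337) for Cela1.

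The genes that keep acinar cells acinar moved with the enzymes. All 20 genes of acinar regulation and secretory identity fell (20 adjusted over the list alone), with a median log2 fold change of -2.90 (camera adjusted p = 2.18e-30, and adjusted p = 0.0634 with an estimated correlation). Ptf1a (chromosome 2, 19445663 to 19447501), the transcription factor that sets acinar identity, fell from 1250.0 ± 456 normalized counts in CD to 163 ± 47.4 in DIO (log2 fold change -2.89 ± 0.36, adjusted p = 0.000694). Bhlha15, a transcription factor of secretory cells, had -3.60 ± 0.32 (adjusted p = 0.000135), and Cckar, the receptor through which cholecystokinin triggers enzyme release, -3.76 ± 0.33 (adjusted p = 0.000135). Fgf21 (Entrez ID 56636; chromosome 7, 45613890 to 45615490), a secreted metabolic hormone that acinar cells also make, fell from 873 ± 513 to 32.7 ± 12.4 (-4.50 ± 0.53, adjusted p = 0.000519). Cth (Entrez ID 107869; chromosome 3, 157894248 to 157925081), which makes cysteine from cystathionine, fell from 1011 ± 98.7 to 47.8 ± 17.4 (-4.43 ± 0.33, adjusted p = 0.000109). Afm (-4.99), Tmed11 (-4.48) and Hamp2 (-4.24) completed the 12 largest falls under the naming rule.

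The lists of protein folding and injury genes were also lower in DIO on the deposited scale. The stress list shares Xbp1 and Dnajc3, and the injury list Nupr1, with the list of acinar regulators. Whether these lists were lower through a lower share of acinar cells was not tested. Of 22 endoplasmic reticulum stress genes, 16 fell and 0 rose (17 and 0 adjusted over the list alone), with a median of -1.55 (camera adjusted p = 3.87e-18, and adjusted p = 0.150 with an estimated correlation). They included the transcription factor Xbp1 (-1.57 ± 0.21, adjusted p = 0.00101), Herpud1 (-2.52 ± 0.33, adjusted p = 0.00103) and the asparagine synthetase Asns (-3.25 ± 0.24, adjusted p = 0.000109). Of 14 genes of the pancreatic injury response, 7 fell (7 adjusted over the list alone), with a median of -1.69 (camera adjusted p = 1.07e-06, and adjusted p = 0.209 with an estimated correlation). Among them were the Reg3 genes, secreted lectins whose close copies can share reads. Reg3b fell from 114693 ± 35346 to 11739 ± 6281 (-3.43 ± 0.49, adjusted p = 0.00176), and Reg3d had -3.85 ± 0.35 (adjusted p = 0.000135). The acute-phase gene Lcn2 did not pass (-0.15 ± 0.42, adjusted p = 0.835). Of 27 nuclear genes of oxidative phosphorylation 9 fell (23 adjusted over the list alone), with a median of -0.88 (camera adjusted p = 3.40e-13, and adjusted p = 0.411 with an estimated correlation). The lower values of the stress, injury and oxidative phosphorylation lists are relative ones. The median log2 fold change of all tested genes was 0.26 on the deposited scale and 2.22 with each library scaled to the same total, and on that second scale the stress list had a median of 0.40, the oxidative phosphorylation list one of 1.06 and the injury list one of -0.06. Relative to all genes, the medians of the stress, oxidative phosphorylation and injury lists were -1.81, -1.14 and -1.95 on the deposited scale and -1.82, -1.16 and -2.28 with equal totals. The enzyme list (-2.04) and the regulator list (-0.96) stayed below 0 there without that correction.

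Transcripts of lymphocytes and of inflammation were higher in DIO. Of 18 T and NK cell genes 2 rose (4 adjusted over the list alone), with a median of 3.16 (camera adjusted p = 0.000723, and adjusted p = 0.544 with an estimated correlation). These were Cd8a, a T cell coreceptor, at 5.90 ± 1.52 (adjusted p = 0.0418), and the immune checkpoint gene Ctla4 at 5.27 ± 1.20 (adjusted p = 0.0261). Of 15 B and plasma cell genes limma called 0 over all genes tested and 1 adjusted over the list alone. Their median was 3.47 (camera adjusted p = 0.00122, and adjusted p = 0.568 with an estimated correlation). Of 13 lymph node genes 0 passed over all genes tested and 7 adjusted over the list alone. Their median was 3.83 (camera adjusted p = 0.00179, and adjusted p = 0.544 with an estimated correlation). The lymph node list held 5 genes with no read in any library of 1 of the 2 groups. Among them was Ccl21a, with 0 reads in DIO 1 to 3 and 0, 0 and 74 in CD 1 to 3, so its lower value in DIO rests on CD 3 alone. The median of the list stayed at 3.83 with these 5 genes set to a bound of 3 reads over the group without reads. With equal library totals camera gave this list the other direction (adjusted p = 0.980), although its median relative to all genes was 3.17. On that scale the camera calls of the T and NK cell (adjusted p = 0.729), B cell (0.910), neutrophil (0.902) and cytokine lists (0.557) also ended, with medians relative to all genes of 2.56, 2.93, 2.85 and 0.92. The call for Cd8a ended in 14 of 21 alternative settings (adjusted p up to 0.157), quantile normalization among them (4.16, adjusted p = 0.0620). The level of the lymph node list differed most within DIO, with a mean log2 level of 9.06, 6.31 and 4.09 in DIO 1 to 3 against 2.52, 2.78 and 3.19 in CD 1 to 3. Of 11 neutrophil genes 0 passed over all genes tested and 0 adjusted over the list alone. Their median was 3.40 (camera adjusted p = 0.0179, and adjusted p = 0.544 with an estimated correlation). Of 23 cytokine and chemokine genes 1 rose (3 adjusted over the list alone), with a median of 1.20 (camera adjusted p = 0.00817, and adjusted p = 0.209 with an estimated correlation). The riser was Cxcl5, a chemokine that draws neutrophils (5.21 ± 1.21, adjusted p = 0.0281), with 271 ± 85.5 normalized counts in DIO and 16.6 ± 22.9 in CD, and its call ended in 7 of 21 settings. Ikzf3, a transcription factor of lymphocytes, had the largest rise under the naming rule (6.97 ± 1.44, adjusted p = 0.0161), from 3503, 856 and 366 reads in DIO 1 to 3 against 0, 0 and 24 in CD 1 to 3.

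The lists of tuft cells, YAP and TAZ targets, interferon and the cell cycle were also higher in DIO, with 1 gene of each passing over all genes tested. Of 12 tuft cell genes 1 rose (5 adjusted over the list alone), with a median of 1.30 (camera adjusted p = 0.00212, and adjusted p = 0.411 with an estimated correlation). It was the tuft cell kinase Dclk1 (1.58 ± 0.30, adjusted p = 0.00945). Of 22 targets of YAP and TAZ 1 rose (7 adjusted over the list alone), with a median of 0.85 (camera adjusted p = 0.00797, and adjusted p = 0.544 with an estimated correlation). It was the matrix protein gene Ccn2 (1.65 ± 0.41, adjusted p = 0.0358). Of 23 interferon response genes 1 rose over all genes tested, Stat2 (0.89 ± 0.23, adjusted p = 0.0439), and 2 adjusted over the list alone. Their median was 0.64 (camera adjusted p = 0.0450, and adjusted p = 0.663 with an estimated correlation). With equal library totals the calls of the interferon and cell cycle lists ended (0.355 for both), and with quantile normalization that of the cell cycle list (0.0533). The libraries of both groups overlapped in the means of the interferon and cell cycle lists (exact permutation p = 0.3 and 0.2). Of 27 cell cycle genes 1 rose, the kinetochore gene Cenpe (4.94 ± 1.31, adjusted p = 0.0460), and 0 adjusted over the list alone. Their median was 0.55 (camera adjusted p = 0.0450, and adjusted p = 0.663 with an estimated correlation). The genes of gastric-type precursor lesions did not shift as a list (camera adjusted p = 0.414). Among them Onecut2 (3.25 ± 0.61, adjusted p = 0.00934), Muc4 (1.85 ± 0.43, adjusted p = 0.0281) and Muc6 (1.28 ± 0.34, adjusted p = 0.0439) rose and the trefoil factor Tff2 fell (-2.61 ± 0.52, adjusted p = 0.0129). Hmgcr, the rate-limiting enzyme of cholesterol synthesis, rose from 335 ± 46.7 to 685 ± 62.4 (1.03 ± 0.25, adjusted p = 0.0348), whereas Insig1 (-1.60 ± 0.24, adjusted p = 0.00255) and Fads2 (-1.10 ± 0.26, adjusted p = 0.0315) of the same list fell. The hyaluronan receptor gene Cd44 of the ductal list (1.15 ± 0.29, adjusted p = 0.0381) and the endothelial receptor gene Kdr (0.85 ± 0.22, adjusted p = 0.0413) rose as well. Other rises under the naming rule were Masp1 (5.70), Nfkbid (5.64), the noncoding RNA Dnm3os (5.16), Jph2 (3.62), Nxpe3 (3.28), Myef2 (3.17), Strip2 (3.14) and Hycc1 (3.06). Masp1 had 0, 0 and 31 reads in CD 1 to 3, Nfkbid 0, 0 and 55, Dnm3os 0, 4 and 62 and Cxcl5 0, 4 and 33, so these fold changes depend on the 1 added before the log and on CD 3. Over the settings they ranged from 3.70 to 7.49 for Masp1, 3.28 to 7.69 for Nfkbid, 3.59 to 6.77 for Dnm3os, 3.80 to 6.76 for Cxcl5 and 4.91 to 8.64 for Ikzf3. Of the 13 rises named by the rule or whatever their result, the calls of Jph2 and Onecut2 held without any single library. The other 11 each ended without at least 1 of CD 1, CD 2, DIO 1, DIO 2 and DIO 3 (adjusted p up to 0.163). Rises named only as examples of a list were not followed over these fits.

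The other 18 lists did not pass in DIO against CD, with camera adjusted p from 0.0544 to 0.884. In alternative settings the islet list gained a call in 7 of 19 (adjusted p down to 7.63e-07), the fibroblast list in 6 (0.00137), the endothelial list in 5 (0.00233), the collagen and matrix list in 4 (5.83e-07) and the others in 0 to 3. Their medians were 0.26 for ductal genes, 0.19 for gastric-type lesion genes, -0.87 for islet genes, 0.30 for collagen and matrix genes, 0.42 for fibroblast genes and 0.01 for macrophage genes. They were -0.21 for adipocyte, 0.39 for endothelial, 0.41 for mesothelial, -1.36 for erythroid, 0.10 for intestinal, -0.27 for liver and 0.21 for Schwann cell genes. The remaining medians were 0.51 for outputs of KRAS and ERK signalling, -0.19 for lipid synthesis, 0.24 for fatty acid oxidation, -0.24 for hypoxia and glycolysis and 0.72 for immediate early genes. Kras had 1056 ± 17.9 normalized counts in DIO and 701 ± 175 in CD (0.62 ± 0.24, adjusted p = 0.126), and without CD 3 the adjusted p was 0.0442. The proliferation gene Mki67 (1.21 ± 0.48, adjusted p = 0.140), the duct genes Krt19 (0.41 ± 0.56, 0.654) and Sox9 (0.18 ± 0.32, 0.743), Muc5ac (0.02 ± 0.81, 0.992) and Yap1 (-0.02 ± 0.26, 0.961) did not pass. Nor did the stroma genes Col1a1 (0.18 ± 0.47, 0.826) and Acta2 (0.33 ± 0.31, 0.50), the macrophage gene Cd68 (0.16 ± 0.30, 0.738), Ptgs2 (3.16 ± 1.56, 0.210) or the hormone genes Cck (3.16 ± 1.41, 0.172), Lep (2.08 ± 2.67, 0.627), Adipoq (-0.22 ± 2.22, 0.957), Ins1 (-1.37 ± 1.14, 0.443) and Ins2 (-1.67 ± 1.19, 0.369).

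Over all 15524 genes tested, limma called 996 genes in DIO against CD, 191 higher and 805 lower, and 14 of 32 lists shifted, of which 0 held with an estimated correlation. On the recovered reads edgeR called 997 genes (148 higher, 849 lower) and DESeq2 2217 (794 higher, 1423 lower). With quantile normalization the split was 392 higher and 946 lower, with array weights 717 and 1060, and with equal library totals it was 12938 higher and 118 lower. Without CD 1, CD 2 or CD 3 the count was 603, 534 or 3078, without DIO 1, DIO 2 or DIO 3 it was 652, 408 or 427, and without both adipocyte-rich libraries, CD 3 and DIO-CD 2, it was 3035 (1587 higher, 1448 lower). The calls of the tuft cell, B cell and cytokine lists ended without CD 3 (adjusted p = 0.0534, 0.0534 and 0.0533), that of the neutrophil list without DIO 2 (0.0660) and that of the YAP and TAZ list without DIO 3 (0.0667). The call of the cell cycle list ended without CD 2, CD 3, DIO 1 or DIO 2 (0.0717, 0.0533, 0.140 and 0.138), and that of the interferon list without CD 1, CD 3, DIO 1 or DIO 2 (0.312, 0.0653, 0.151 and 0.125).

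**Figure D2:**
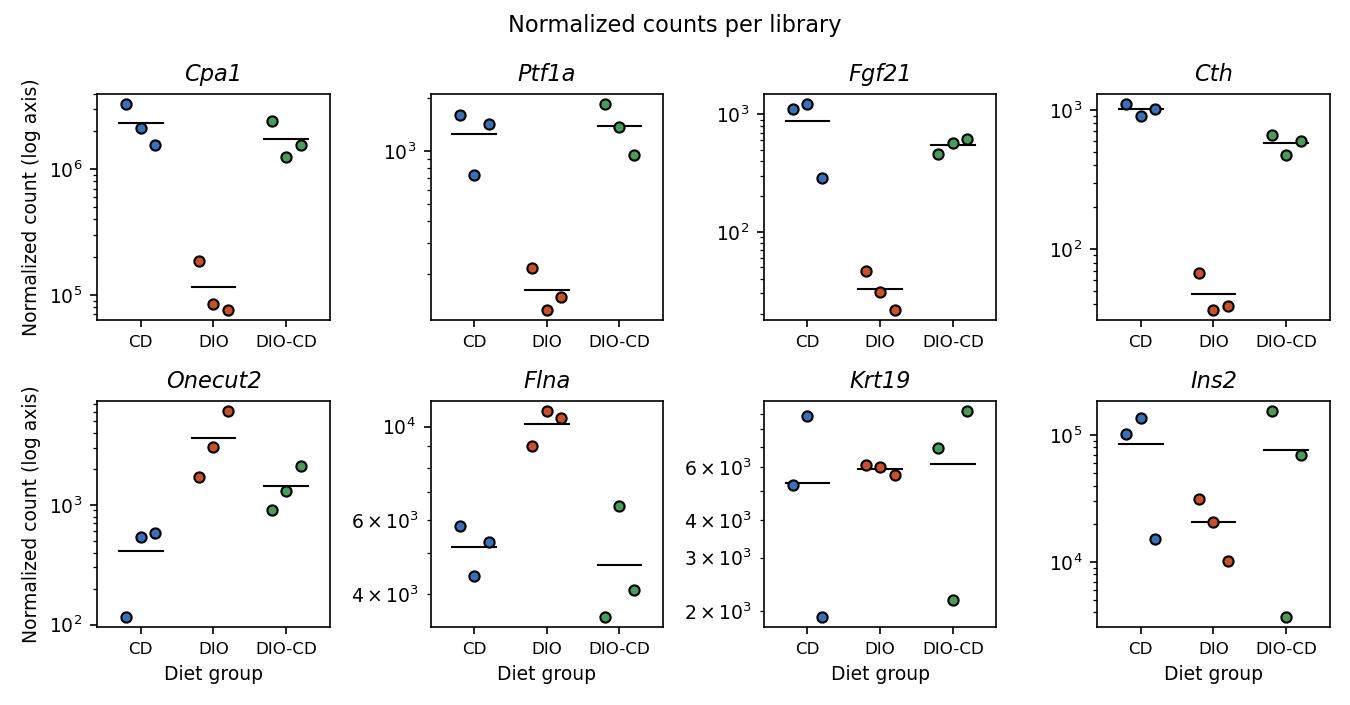
Normalized counts (log axis) of 8 genes in each of the 9 libraries (points), with the mean of each diet group (bars, n = 3). Cpa1, Ptf1a, Fgf21 and Cth are lower in all 3 DIO libraries than in the other 6 and Flna is higher, while Krt19 and Ins2 overlap between groups.

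The second comparison, DIO-CD against DIO, asks how mice that left the high-fat diet differ from those that stayed on it. Its main result was that acinar cell transcripts were higher in DIO-CD. All 31 digestive enzymes had higher levels in DIO-CD, and 16 rose over all genes tested (30 adjusted over the list alone), with a median of 3.61 (camera adjusted p = 2.56e-33, and adjusted p = 0.229 with an estimated correlation). The median was 1.28 with quantile normalization. Pla2g1b rose from 2148 ± 692 to 42332 ± 9844 (4.32 ± 0.53, adjusted p = 0.000790), and the amylase copies Amy2a1 (4.49), Amy2a2 (4.60), Amy2a3 (4.03) and Amy2a5 (4.21) rose with the same doubt about shared reads. Cpa1 had 1756920.0 ± 611712 normalized counts in DIO-CD and 114967 ± 60345 in DIO, which did not pass (4.00 ± 1.11, adjusted p = 0.0966). Its log2 fold change was 0.60 (adjusted p = 0.637) with quantile normalization and 2.44 (0.00511) with equal library totals. Of the 20 acinar regulators 18 rose (20 adjusted over the list alone), with a median of 2.96 (camera adjusted p = 6.64e-39, and adjusted p = 0.0333 with an estimated correlation), the only list of the 32 that held with an estimated correlation in this comparison. Ptf1a rose from 163 ± 47.4 to 1391 ± 452 (3.07 ± 0.36, adjusted p = 0.000619) and Fgf21 from 32.7 ± 12.4 to 548 ± 78.1 (4.08 ± 0.53, adjusted p = 0.00114). Tmed11 (4.49), Hamp2 (4.04), the serotonin transporter Slc6a4 (3.98), Azgp1 (3.91) and the zinc transporter Slc39a5 (3.87) were among the largest rises, as was Afm (4.03), whose call ended without DIO 1, DIO 2, DIO-CD 1, DIO-CD 2 or DIO-CD 3 (adjusted p up to 0.163).

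The stress, injury and oxidative phosphorylation lists, lower in DIO than in CD, were higher in DIO-CD than in DIO, as was the islet list, which had not passed in DIO against CD (adjusted p = 0.0544, under 0.05 in 7 of 19 settings). A different share of acinar cells was not tested as a source of these shifts either. Of 22 endoplasmic reticulum stress genes 9 rose (16 adjusted over the list alone), with a median of 1.30 (camera adjusted p = 3.80e-16, and adjusted p = 0.130 with an estimated correlation). Of 14 injury genes 6 rose (7 adjusted over the list alone), with a median of 1.44 (camera adjusted p = 3.29e-05, and adjusted p = 0.283 with an estimated correlation). Among them were Reg3d (2.85 ± 0.35, adjusted p = 0.000818) and Reg3b (2.37 ± 0.49, adjusted p = 0.0232). The call for Reg3b ended without DIO 2, DIO 3, DIO-CD 1 or DIO-CD 3 (0.0583, 0.104, 0.115 and 0.140), with quantile normalization (0.0601) and with equal library totals (0.165). The oxidative phosphorylation list had 0 genes passing over all genes tested and 15 adjusted over the list alone, with a median of 0.71 (camera adjusted p = 1.06e-11, and adjusted p = 0.412 with an estimated correlation). The islet list had 0 and 0, with a median of 0.86 (camera adjusted p = 0.00482, and adjusted p = 0.701 with an estimated correlation). Its call ended without DIO-CD 1 or DIO-CD 3 (adjusted p = 0.552 and 0.0545), and its median relative to all genes ranged from 0.09 to 2.24 over the 19 settings. With equal library totals the median of all genes was -1.70 in place of -0.14, and the medians of the stress (-0.26), oxidative phosphorylation (-0.85) and islet (-0.70) lists turned negative. Relative to all genes they stayed positive there, at 1.44, 0.86 and 1.01. The median of the injury list was 0.29 with equal totals, and 2.00 relative to all genes.

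Matrix, stromal, immune and signalling lists shifted the other way, with 0 single genes passing in any of these 13 lists over all genes tested and 1 adjusted over the list alone (in the tuft cell list). In the list means, the libraries of both groups overlapped for the collagen, macrophage, T cell, B cell and lymph node lists. They also overlapped for the cell cycle, KRAS and ERK, YAP and TAZ and immediate early lists (exact permutation p from 0.2 to 0.5 over these lists). The 95% interval of the mean included 0 for all of these but the KRAS and ERK and immediate early lists, and for the tuft cell list. B and plasma cell genes had a median of -2.12 (camera adjusted p = 0.00175, and adjusted p = 0.589 with an estimated correlation). Neutrophil genes had a median of -1.81 (camera adjusted p = 0.00676, and adjusted p = 0.415 with an estimated correlation). Lymph node genes had a median of -1.50 (camera adjusted p = 0.0169, and adjusted p = 0.589 with an estimated correlation). T and NK cell genes had a median of -1.18 (camera adjusted p = 0.0103, and adjusted p = 0.589 with an estimated correlation). Cytokines and chemokines had a median of -1.04 (camera adjusted p = 0.00116, and adjusted p = 0.130 with an estimated correlation). Collagen and matrix genes had a median of -0.81 (camera adjusted p = 3.46e-08, and adjusted p = 0.429 with an estimated correlation). Their mean was -0.83 (95% interval -1.81 to 0.14), and the mean log2 level in DIO 1 (11.23) lay below that in DIO-CD 2 (11.55) and DIO-CD 3 (11.29). Of the matrix genes, the proteoglycan genes Lum (-0.84 ± 0.23) and Bgn (-1.11 ± 0.34) did not pass alone (adjusted p = 0.0891 and 0.132). Cell cycle genes had a median of -0.77 (camera adjusted p = 0.00116, and adjusted p = 0.462 with an estimated correlation). Tuft cell genes had a median of -0.73 (camera adjusted p = 0.0104, and adjusted p = 0.429 with an estimated correlation). Outputs of KRAS and ERK signalling had a median of -0.72 (camera adjusted p = 0.00417, and adjusted p = 0.412 with an estimated correlation). Fibroblast genes had a median of -0.68 (camera adjusted p = 5.71e-05, and adjusted p = 0.412 with an estimated correlation). Immediate early genes had a median of -0.58 (camera adjusted p = 0.0351, and adjusted p = 0.429 with an estimated correlation). Targets of YAP and TAZ had a median of -0.54 (camera adjusted p = 0.00482, and adjusted p = 0.429 with an estimated correlation). Macrophage genes had a median of -0.42 (camera adjusted p = 0.00374, and adjusted p = 0.517 with an estimated correlation). With equal library totals camera gave the T cell, B cell and lymph node lists the other direction (adjusted p = 0.549, 0.997 and 0.498), with medians relative to all genes of -0.95, -1.90 and -1.34. On that scale the calls of the neutrophil (0.498), cytokine (0.333), tuft cell (0.148) and cell cycle lists (0.124) ended. The calls of the T cell, B cell and lymph node lists ended without DIO 1 (adjusted p = 0.524, 0.116 and 0.524), and those of the B cell and lymph node lists also without DIO-CD 1 (0.0778 and 0.118). Over all 19 settings the medians of these 3 lists relative to all genes ranged from -1.63 to -0.27, from -3.65 to -0.78 and from -2.46 to -0.31. Those of the tuft cell (0.118), KRAS and ERK (0.0664), YAP and TAZ (0.118) and immediate early lists (0.0664) ended without DIO 3, those of the macrophage (0.236) and immediate early lists (0.0951) without DIO 2, and those of the tuft cell (0.129) and immediate early lists (0.146) without DIO-CD 2.

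Single genes that fell in DIO-CD against DIO numbered 9. Flna (chromosome X, 74223461 to 74249854), which crosslinks actin filaments, fell from 10125 ± 1014 to 4697 ± 1569 (-1.15 ± 0.25, adjusted p = 0.0317). The matrix protein gene Ltbp2 had -1.73 ± 0.31 (adjusted p = 0.0108), the small GTPase gene Arl4c -1.61 ± 0.28 (0.00779), the thrombin receptor F2r -1.55 ± 0.30 (0.0159) and the adhesion molecule Vcam1 -1.43 ± 0.32 (0.0346). The others were Csf2rb2 (-2.03), Atp8a1 (-1.51), Mylk (-1.46) and Cyp1b1 (-1.38). Only the call of Arl4c among these 9 held without any single library of the 6 compared, and the other 8 ended without at least 1 of DIO 1, DIO 2, DIO 3, DIO-CD 1 and DIO-CD 3 (adjusted p up to 0.233). Of the genes named whatever their result, Kras (-0.54 ± 0.24, adjusted p = 0.324), Hmgcr (-0.80 ± 0.25, 0.152), Mki67 (-0.89 ± 0.48, 0.439), Krt19 (-0.19 ± 0.56, 0.918), Sox9 (0.03 ± 0.32, 0.977), Muc5ac (0.66 ± 0.81, 0.760) and Yap1 (0.27 ± 0.26, 0.672) did not pass. The same held for Col1a1 (-0.72 ± 0.47, 0.526), Acta2 (-0.64 ± 0.31, 0.390), Cd68 (-0.32 ± 0.30, 0.665), Lcn2 (-0.45 ± 0.42, 0.666), Ptgs2 (-3.13 ± 1.56, 0.399), Cck (-0.95 ± 1.41, 0.811), Lep (-0.73 ± 2.67, 0.933), Adipoq (-1.75 ± 2.22, 0.771), Ins1 (1.07 ± 1.14, 0.718) and Ins2 (0.86 ± 1.19, 0.795).

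Over all genes, limma called 432 in DIO-CD against DIO, 423 higher and 9 lower, and 19 of 32 lists shifted, 6 higher and 13 lower. On the recovered reads edgeR called 466 genes (461 higher, 5 lower) and DESeq2 1006 (884 higher, 122 lower), and with equal library totals the split was 135 higher and 9183 lower. Quantile normalization gave 560 higher and 51 lower, and array weights 1346 and 567. The count was 214 without DIO 2, 242 without DIO 3, 186 without DIO-CD 1, 221 without DIO-CD 3 and 892 without both adipocyte-rich libraries (750 higher, 142 lower). The 13 lists that did not pass had camera adjusted p from 0.0933 to 0.887, of which the ductal and adipocyte lists gained a call in 5 of 19 settings each and the others in 0 to 3.

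The third comparison, DIO-CD against CD, asks what remains of the earlier high-fat diet. No single gene passed in the main limma fit, while some other fits called genes, as given below. The digestive enzymes had a mean log2 fold change of -0.42 (95% interval -1.64 to 0.80) and the acinar regulators one of -0.21 (-0.68 to 0.27). Ptf1a had 1391 ± 452 normalized counts in DIO-CD and 1250.0 ± 456 in CD (0.18 ± 0.36, adjusted p = 0.913), Fgf21 548 ± 78.1 and 873 ± 513 (-0.42 ± 0.53, 0.852) and Cpa1 1756920.0 ± 611712 and 2341870.0 ± 898168 (-0.40 ± 1.11, 0.944). Among genes that met the other conditions of the naming rule, those with the smallest unadjusted p on the higher side were Jph2 (2.64 ± 0.58), the RNA-binding protein gene Ewsr1 (0.84 ± 0.20), Osr2 (2.42 ± 0.61), the splicing factor Srsf5 (0.76 ± 0.20), Strip2 (2.21 ± 0.59) and Ikzf3 (5.39 ± 1.44). On the lower side they were Lrrn4cl (-1.32 ± 0.34), Elac2 (-0.97 ± 0.27), Sec13 (-0.80 ± 0.22), Lrpprc (-0.91 ± 0.26), Tspan4 (-1.09 ± 0.31) and Ap2m1 (-0.76 ± 0.22), and all 12 had an adjusted p of 0.756. Ikzf3 passed without CD 3 (7.05, adjusted p = 0.0479), and Jph2 passed with DESeq2 on the recovered reads (2.59, adjusted p = 0.0237). Kras (0.08), Hmgcr (0.24), Reg3b (-1.06), Lcn2 (-0.60), Mki67 (0.32), Krt19 (0.22), Sox9 (0.21), Muc5ac (0.68), Col1a1 (-0.54), Acta2 (-0.30), Cd68 (-0.16), Yap1 (0.25), Ptgs2 (0.02), Cck (2.22), Lep (1.36), Adipoq (-1.96), Ins1 (-0.30) and Ins2 (-0.81) did not pass either (adjusted p 0.756 to 0.998).

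As lists, 11 of 32 shifted in DIO-CD against CD with 0 single genes passing in each, over all genes or adjusted over the list alone, and 0 of the 11 held with an estimated correlation. The 95% interval of the mean included 0 for each of the 11. T and NK cell genes were higher, with a median of 1.70 (camera adjusted p = 0.0146, and adjusted p = 0.735 with an estimated correlation), as were lymph node genes, with a median of 1.79 (camera adjusted p = 0.0156, and adjusted p = 0.735 with an estimated correlation). The medians were 1.91 and 2.35 when genes with no read in any library of 1 of the 2 groups were set to a bound of 3 reads over that group. These values lie above the fitted medians and so are no lower limit to them. Collagen and matrix genes were lower, with a median of -0.50 (camera adjusted p = 5.21e-07, and adjusted p = 0.726 with an estimated correlation). So were macrophage genes, with a median of -0.47 (camera adjusted p = 4.51e-06, and adjusted p = 0.697 with an estimated correlation). Stress genes were lower with a median of -0.40 (camera adjusted p = 4.07e-06, and adjusted p = 0.697 with an estimated correlation), and injury genes with a median of -0.80 (camera adjusted p = 0.000794, and adjusted p = 0.697 with an estimated correlation). With equal library totals, which moved the median of all genes from 0.10 to 0.48, the medians of these lower lists were -0.11 (collagen and matrix), -0.08 (macrophage), -0.01 (stress) and -0.41 (injury). Relative to all genes they were -0.59, -0.57, -0.50 and -0.90 there. Quantile normalization ended the call of the injury list (adjusted p = 0.0980). The medians of the other 5 lower lists rose with the same shift of all genes, and relative to all genes they stayed below 0. Oxidative phosphorylation had a median of -0.23 (camera adjusted p = 0.00125, and adjusted p = 0.735 with an estimated correlation), against 0.16 with equal library totals (-0.32 relative to all genes). Digestive enzymes had a median of -0.40 (camera adjusted p = 0.00508, and adjusted p = 0.806 with an estimated correlation), against -0.02 (-0.50). Lipid synthesis had a median of -0.28 (camera adjusted p = 0.0131, and adjusted p = 0.697 with an estimated correlation), against 0.11 (-0.38). Acinar regulators had a median of -0.30 (camera adjusted p = 0.0146, and adjusted p = 0.729 with an estimated correlation), against 0.09 (-0.39). Fibroblast genes had a median of -0.23 (camera adjusted p = 0.0155, and adjusted p = 0.729 with an estimated correlation), against 0.16 (-0.33). The enzyme list's median was 0.06 with quantile normalization. That setting also ended the calls of the T cell (0.0782), lymph node (0.132), regulator (0.943), fibroblast (0.270), lipid synthesis (0.0980) and oxidative phosphorylation lists (0.170). Equal library totals ended the calls of those same 6 lists (0.0924, 0.155, 0.207, 0.0930, 0.0512 and 0.390). The calls of the T cell and lymph node lists ended without CD 3 (adjusted p = 0.0892 and 0.155) or DIO-CD 2 (0.326 for both). Those of the enzymes, regulators and oxidative phosphorylation ended without CD 1 (0.873, 0.298 and 0.557) or DIO-CD 2 (0.117, 0.354 and 0.299). That of lipid synthesis ended without CD 3 or DIO-CD 3 (0.209 and 0.102) and that of fibroblasts without CD 1 or DIO-CD 1 (0.405 and 0.167). The 21 lists that did not pass had camera adjusted p from 0.0532 to 0.897, of which the tuft cell and endothelial lists gained a call in 5 of 19 settings each and the others in 0 to 3. For single genes limma called 0 of 15524, with 966 at an unadjusted p under 0.05, edgeR called 0 (673 at an unadjusted p under 0.05) and DESeq2 called 4 (961). Those 4, outside the naming rule except for Jph2 and named after their values were seen, were Ptprv (6.74), Glyctk (6.90), Fam227a (4.98) and Jph2 (2.59), where Ptprv and Glyctk had no read in any CD library, so that their fold changes depend on the fit. Without CD 3 limma called 66, all higher.

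**Figure D3:**
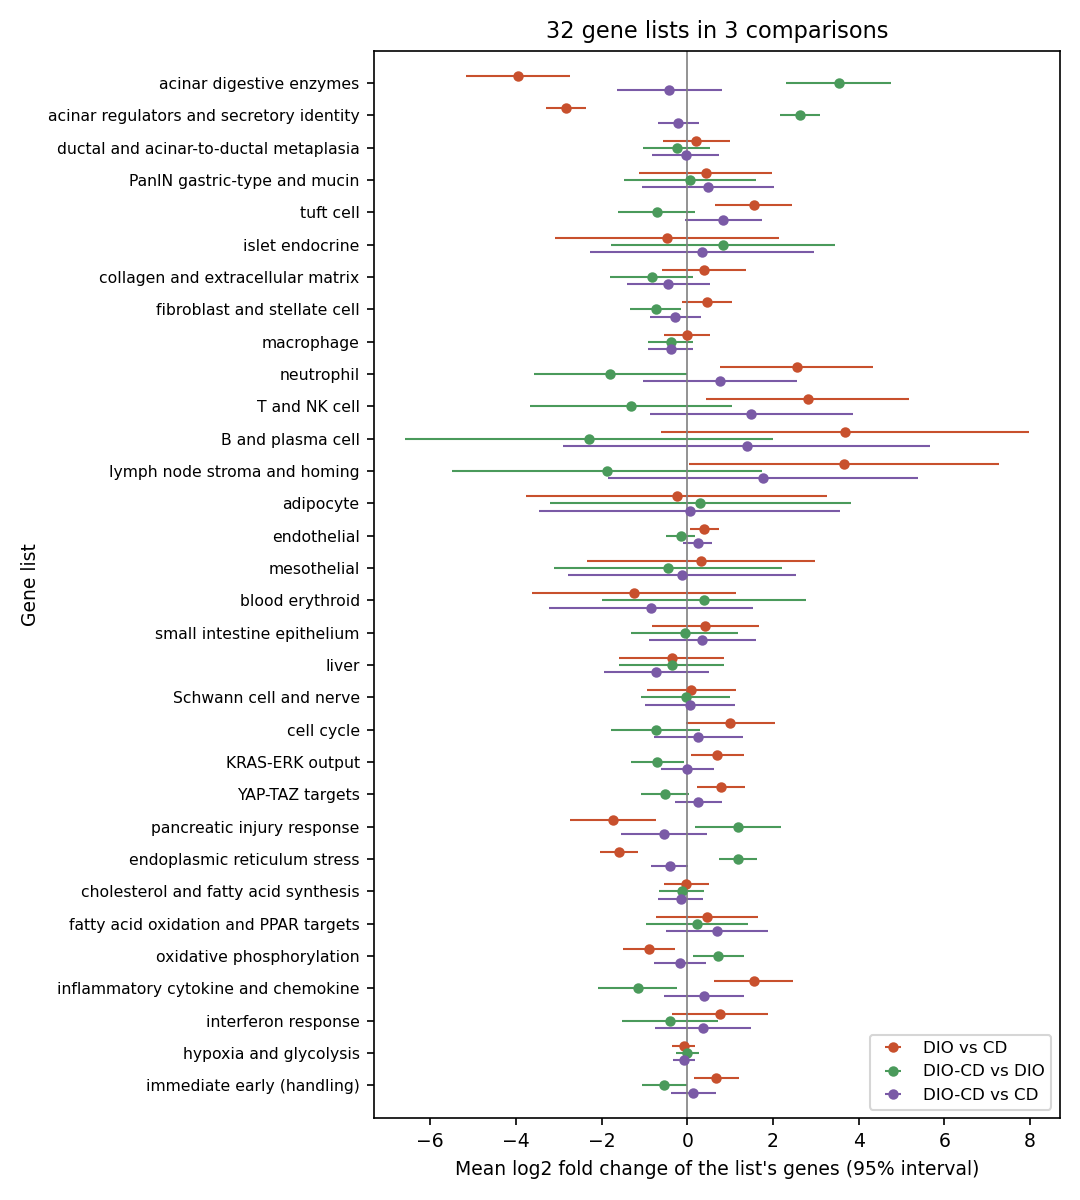
Mean log2 fold change of the genes of each of the 32 lists (points) with its 95% interval (lines) in the 3 comparisons, on the deposited scale. The enzyme and regulator intervals lie below 0 for DIO against CD and above 0 for DIO-CD against DIO, and include 0 for DIO-CD against CD.

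Across the comparisons, many genes lower in DIO than in CD were higher in DIO-CD than in DIO. No library was taken at the change of diet. The values therefore do not show whether these genes had fallen in DIO-CD mice before the change and then rose. Of the 805 genes lower in DIO than in CD, 397 were among the 423 higher in DIO-CD than in DIO, against 21.9 from independent lists of these sizes, and 8 of the 9 genes lower in DIO-CD than in DIO were among the 191 higher in DIO than in CD, against 0.111. Genes called in the same direction in both numbered 0 for higher and 0 for lower genes, against 5.20 and 0.467 from independent lists. Simulated unchanged groups that share the DIO libraries also gave 0 for both in each of 1000 draws, so these 0 counts are no evidence of opposite effects. In 1000 simulated draws of unchanged groups, which share the DIO libraries as here, the mean overlaps in opposite directions were 1.80 and 0.843 genes, and 1 draw reached 397 and 3 reached 8. Neither value holds both the shared libraries and real effects, so part of the excess may come from the shared libraries. The 805 lower genes had a median log2 fold change of -1.59 in DIO against CD, 1.32 in DIO-CD against DIO and -0.30 in DIO-CD against CD, and the 191 higher genes had medians of 1.67, -0.91 and 0.83. Both comparisons share the DIO libraries, so opposite signs arise in part by construction. Across the 15524 genes, which are not independent replicates, the log2 fold changes of DIO against CD and DIO-CD against DIO had Pearson r = -0.692, against a median of -0.560 and a range from -0.939 to 0.528 in 95% of 1000 simulated draws of unchanged groups. Their covariance was -0.913, against a simulated mean of -0.367 (range -1.29 to 0.216). For DIO against CD and DIO-CD against CD, which share the CD libraries, r was 0.699, against 0.568 (-0.423 to 0.936), and the covariance was 0.930, against 0.372 (-0.207 to 1.33). Both correlations and both covariances lie within the simulated ranges. Among the 3 diets, limma's F test called 549 genes, edgeR 524 and DESeq2 1576, and the limma count was 1733 without CD 3, 260 without DIO 2 and 273 without DIO 3.

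**Figure D4:**
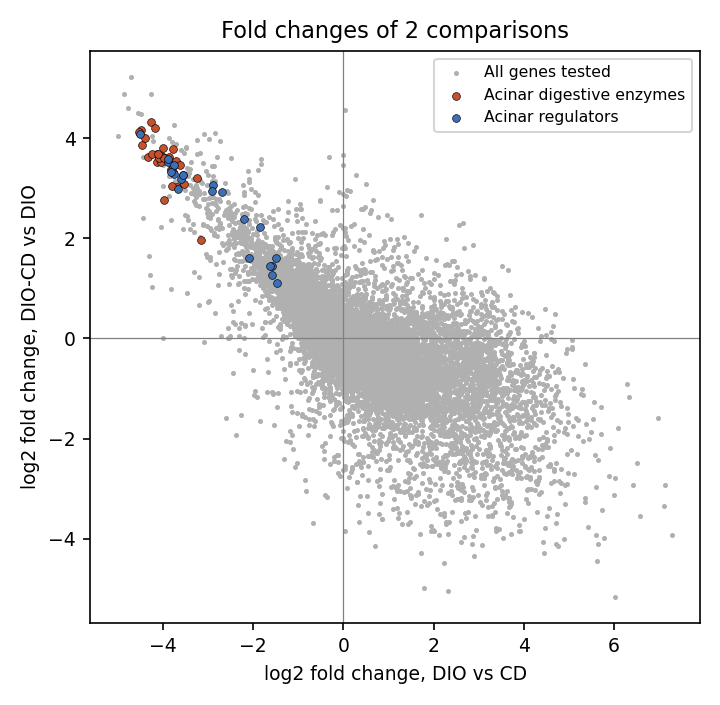
Log2 fold change of DIO against CD (x axis) and of DIO-CD against DIO (y axis) for the 15524 genes tested (grey points), with the 31 digestive enzymes and 20 acinar regulators in colour, on the deposited scale. The coloured genes lie together at the upper left, and r across all genes is -0.692.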

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

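The fits on thinned reads and without CD 3 and DIO-CD 2 were chosen only after the results were seen. Over 117 results for named genes and 2451 alternative values, 2130 kept direction and side of the threshold, 186 lost the call, 38 gained one, 4 reversed and 93 changed the sign of a value without a call. Over 96 list results and 1824 values the counts were 1479, 162, 77, 11 and 95. Kept values include uncalled results that stayed uncalled, so these counts do not measure how stable the calls were. A reversed value took the other direction, with a call in the main fit or in the alternative. Causes of the changes below were not tested except where the construction of an alternative shows them.

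With equal library totals the counts were 13056 genes (305 shared with the 996) in DIO against CD, 9318 (129 shared with the 432) in DIO-CD against DIO and 11662 among the 3 diets, because this scale shifts all genes together (median log2 fold change 2.22 in place of 0.26 for DIO against CD). On it Lcn2 (1.80) and Yap1 (1.92) in DIO against CD and Sox9 (-1.53) and Yap1 (-1.29) in DIO-CD against DIO passed with the other sign. On the deposited scale these 4 results were not called (-0.15, -0.02, 0.03 and 0.27, limma adjusted p from 0.672 to 0.977). For lists, the direction of the camera test turned against its direction on the deposited scale, while the median relative to all genes was 3.17 (lymph node), 0.12 (mesothelial) and -1.16 (oxidative phosphorylation) in DIO against CD, and -0.95 (T and NK cell), -1.90 (B cell), -1.34 (lymph node), 0.86 (oxidative phosphorylation) and 0.0792 (hypoxia) in DIO-CD against DIO. Quantile normalization reversed the enzyme list in DIO-CD against CD (0.0630) and left 4 lists shifted there. Without DIO-CD 1 the islet list in DIO-CD against CD passed in the other camera direction (-0.86, with a range to 1.20 over the libraries left out). So did the gastric-type lesion list in DIO-CD against DIO without both adipocyte-rich libraries (0.82, against 0.08 with all libraries, relative to all genes). In the main fit neither list was called (camera adjusted p = 0.714 and 0.887).

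Counts of genes for DIO against CD, DIO-CD against DIO and the 3 diets were 1777, 1913 and 864 with array weights, 488, 245 and 327 with no trend, 3035, 892 and 1977 without the adipocyte-rich libraries, and 2217, 1006 and 1576 with DESeq2. The fit over 6 samples gave 528 for DIO against CD. DIO-CD against CD gave 11 with no trend and 4 with DESeq2. Lists shifted numbered 0, 1 and 0 in the 3 comparisons with an estimated correlation and 7, 5 and 0 with the directional test of fry (camera 14, 19 and 11), and 7 in DIO-CD against CD with array weights and 7 without the adipocyte-rich libraries. With the replicate number as a block the counts were 807 genes (740 shared), 383 (351 shared), 0 and 512. Residual correlations of libraries with the same number were -0.196 to 0.0862, and 0 of 9 exceeded 0.1, against 3 of 18 for other pairs, so the numbers gave no sign of pairing.

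With each library left out in turn, genes ranged from 408 (without DIO 2) to 3078 (without CD 3) for DIO against CD, from 186 (without DIO-CD 1) to 507 for DIO-CD against DIO, from 0 to 66 (without CD 3) for DIO-CD against CD and from 260 (without DIO 2) to 1733 (without CD 3) among the diets. Other counts over 1.5 times away were 603, 534, 652 and 427 without CD 1, CD 2, DIO 1 and DIO 3 for DIO against CD, 214, 242 and 221 without DIO 2, DIO 3 and DIO-CD 3 for DIO-CD against DIO, and 273 without DIO 3 among the diets. Lists ranged from 11 to 17, 16 to 20 and 10 to 14, and the correlations across genes from -0.716 to -0.605 and from 0.501 to 0.818. Without both adipocyte-rich libraries Ins1 and Ins2 passed in DIO against CD (-2.28 and -2.66), and Mki67 did (1.49). Among genes with a mean of 50 to 100, CD 1 had 22.3% zeros after thinning to equal worth per read, against 1.98% in DIO-CD 3, so depth alone does not account for its zeros.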

Other observations

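The amino acid gene list, the test of the scaling, the relation to lymph node genes, and the thinned reads were chosen only after the results were seen. Of 25 genes of amino acid synthesis and transport, listed because several stood among the called genes and so no independent evidence of their direction, 20 fell and 0 rose in DIO against CD (limma, over all genes tested; median log2 fold change -2.88). Scaled to equal library totals, 12 fell and 4 rose, with a median of -0.94 (-3.12 relative to all genes). The 20 included Asns, which makes asparagine (-3.25 ± 0.24, SE), Cbs, which makes cystathionine (-3.59 ± 0.29), the glutaminase gene Gls2 (-2.88 ± 0.22), Phgdh and Psat1 of serine synthesis (-3.04 ± 0.33 and -2.68 ± 0.32) and the amino acid transporter gene Slc7a5 (-2.96 ± 0.34). Psph (-1.05), Got1 (-0.45), Slc1a5 (-0.43), Slc7a2 (-0.19) and Slc7a11 (-0.00) did not pass. In DIO-CD against DIO 19 of the 25 rose (median 2.43), and with equal library totals 13 rose and 3 fell (0.87). In DIO-CD against CD, where limma called 0 of all genes (966 at an unadjusted p under 0.05) and edgeR 0 and DESeq2 4, the median was -0.34. It was -0.19 with quantile normalization and 0.04 with equal library totals (-0.43 relative to all genes).

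The lower level of the enzyme list in DIO than in CD was weighed against 2 explanations. The tables argue against scaling by size factors as the whole cause, since the median log2 fold change was -2.039 with equal library totals and -1.19 with quantile normalization, against -3.99 before, although the latter left Cpa1 at -0.49 (adjusted p = 0.627), so the size of the difference depends on the scale. A lower share of acinar cells stays open and cannot be told apart from lower expression within them. It would raise markers of all other cell types alike. With intervals widened for 12 lists (Bonferroni, members with a mean of at least 200), 0 of 12 left out the median of all genes (0.26). These intervals were wide (means from -0.80 to 4.51). The 95% intervals over all members, not widened, left it out for tuft cell (0.66 to 2.46), neutrophil (0.76 to 4.35) and T and NK cell lists (0.44 to 5.18). Those of the other cell types included it, so the test does not decide.

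The higher lymphoid, neutrophil and cytokine lists in DIO than in CD (79 members, median 2.53) were weighed against 3 technical or anatomical explanations. Thinning to equal worth per read left a median of 2.443, which argues against fewer reads per transcript in CD. It left 0.192% to 0.640% zeros in the DIO libraries among genes with a mean of 50 to 100, against 22.3%, 9.35% and 2.30% in CD 1 to 3. In DIO-CD 1 to 3 the zeros were 5.89%, 0.256% and 1.98%. The zeros in CD 1 and CD 2 thus have another source that was not found. The median stood at percentile 100 of 10000 random lists matched on level (median 0.436, central 95% from 0.157 to 0.740), so genes of like level typically shifted less. The percentile does not decide on a general loss of low-level transcripts. The 5 lists were picked because they were higher, and random genes lack the correlation within lists (estimated at 0.415 for T and NK cell, 0.685 for B cell and 0.515 for lymph node genes). Lymph node tissue or lymphoid aggregates in some libraries stay open and cannot be told apart from B cells of another origin, since across the 9 libraries the B cell list deviated from its group means with 5 stromal and vessel genes of the lymph node list at Pearson r = 0.798 (permutation p = 0.0324; Spearman rho = 0.717, permutation p = 0.0602; 216 arrangements, 2 relations computed; r = 0.638 without DIO 1 and DIO 3), while r = 0.951 with all 13 lymph node genes includes genes that B cells express themselves. Of these 5 genes, Glycam1 had 15202, 12 and 10 reads in DIO 1 to 3 against 0, 0 and 0 in CD 1 to 3. Cxcl13 had 1672, 657 and 32 against 32, 0 and 10, and Madcam1 1010, 509 and 193 against 14, 22 and 23. Chst4 had 203, 242 and 122 against 2, 10 and 16, while Ccl21a had 0, 0 and 0 against 0, 0 and 74. Most of the Glycam1 reads thus lay in DIO 1. Whether immune cells entered the pancreas with the diet was not tested and stays open.

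Other splits of the 6 libraries of a comparison number 10 with the real one, too few for a share under 0.05. The real split of DIO and CD gave 996 genes and the highest other 0 (1 of 10 gave as many), and for lists 14 and 17 (3 of 10). For DIO-CD and DIO they gave 432 genes and 0 (1 of 10), and 19 and 20 lists (3 of 10). For DIO-CD and CD they gave 0 genes and 1 (10 of 10), and 11 and 12 lists (4 of 10). Among 100 splits of the 9 libraries into 3 groups, the real one included, 2 gave at least the 549 genes of the diets by limma's F test. This share is under 0.05 but does not exclude chance. The 3 other splits that kept the DIO libraries together gave 1092, 532 and 453, against 14 at most for the 96 that did not, so the count does not tell CD from DIO-CD.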
